A study of Mus musculus with 3 samples.

How the data were processed

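Whole lungs of mice carrying loxP-flanked Lin28a and Lin28b and an inducible Cre recombinase, and of a wild type, were profiled by RNA sequencing. Per the labels, total RNA was extracted with Trizol and libraries were made with the SMARTer Ultra Low Input kit, which amplifies full-length cDNA. Per the submitters' processing notes, the tools used were cutadapt, TopHat2, HTSeq and edgeR with genome build mm10, and their versions and order are not given in the sources used here. The authors deposited RPKM values, reads scaled to transcript length and library depth, for RefSeq transcripts, with 1 column per library. The gene annotation, the transcript lengths and the total used for scaling are not given in the sources used here. Whether reads were assigned by strand is likewise not given, so overlapping and antisense genes are uncertain.

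The table holds 16383 transcripts in order of their identifiers, from NM_001001144 to NM_015816. Transcripts with later identifiers, including Lin28a, were not analysed here. A RefSeq gene table (GRCm38.p6) named 16151 of them and the GENCODE annotation of the same build a further 77, leaving 155 unnamed. A share of 68.0% was listed at 0 in all 3 libraries. That share grew with the number of RefSeq transcripts of the gene, from 47.8% for genes with 1 transcript to 67.8% for 2 transcripts and 90.0% for 6 or more. Gapdh, a gene that nearly every cell uses, had 0.0144 RPKM in WT, 0.115 in DKO 1 and 0.185 in DKO 2, so a 0 or a very low value can be a failed estimate where transcripts overlap. For that reason genes are described as listed at 0, each library's value is given, and no fold is given against 0. Such transcripts stay in the list medians, which then depend on the pseudocount.

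RPKM are not counts. RPKM was multiplied by annotated transcript length in kilobases, and the commonest low value of this product was taken as the worth of 1 read. It was sought within a fixed window, which bounds the depth that could be found, and then refined. The product for 1 read was 0.0205 in WT, 0.0326 in DKO 1 and 0.0292 in DKO 2. These products imply about 48700000, 30700000 and 34200000 reads. Of the values of 1 to 100 reads, 45.7%, 45.2% and 43.9% lay within 0.05 of a whole read in the same order, where 10% would by chance, and what kept the others from whole reads was not tested. Read numbers are therefore approximate and were used for intervals and 1 alternative fit. Intervals are at the 95% level and cover counting error only, since reads amplified by PCR are not independent molecules.

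The groups were taken from the genotype labels, with 1 WT and 2 DKO libraries. Values were analysed as log2(RPKM + 1), and transcripts with a mean of at least 1 RPKM over the libraries were kept, which left 2066. Fold changes on this scale understate changes of low genes. The test was limma 3.58.1 in R 4.3.3 (linear fit and empirical Bayes moderation with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). It had 1 residual degree of freedom, which came from the 2 DKO libraries, and a prior of 11.2. A rule of size, at least 2-fold from WT in the same direction in both DKO libraries with these differing from each other by less than the smaller difference, was counted beside it, with no p.

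Before the data were examined, 46 gene lists were fixed, for epithelial cell types, signalling pathways, let-7 targets, other lung cell types, blood, neighbouring organs and general cell functions. Of these, 28 had at least 5 tested transcripts and were tested with camera at its preset correlation of 0.01, 12 had 1 to 4 and 6 had none. Each tested list was also set against 10000 random lists of the same size and expression level, as a description of these libraries. The genes named in the text follow a rule fixed at the same time. It takes Lin28a, Lin28b and Nkx2-1, then the 12 highest and 12 lowest genes by the smaller of the differences in the 2 DKO libraries, leaving out predicted genes, and then up to 4 members of each described list that lay on the same side of WT in both. Krt18, Spry2, Gata6, C1qc, Myl2, Kdm5d, Uty, Gapdh, Hbb-y, Afp, Myl4 and Stfa1 were added after their values were seen. A single gene that the rule takes is not reported here.

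The procedure was tested on simulated data of 2049 transcripts, with 200 changed in each of 10 simulations. Limma recovered 31.6%, 92.5% and 99.4% of changes of 4, 16 and 64-fold, and called 7.4 unchanged transcripts per simulation. A shifted list of 12 transcripts was called in 8 of 10 simulations.

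Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, median scaling, quantile normalization, rescaling to TPM, moderation without a trend or with robust estimation, removal of haemoglobin, mitochondrial and sex-linked genes, a 1.5-fold rule, list tests with an estimated correlation, on ranks or with fry, and leaving out each DKO library. The removal of haemoglobin, mitochondrial and sex-linked genes was followed by rescaling the remaining transcripts to each library's former RPKM total. No mitochondrially encoded or female-linked gene was among the transcripts, so it took out haemoglobin and Y-linked genes only. Alternatives chosen after seeing the data were genes with 1 RefSeq transcript, removal of the trend with GC content, voom on approximate reads, and lists without Sftpc or without transcripts listed at 0 in WT.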

Results

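The libraries came from whole mouse lung of a mixed C57BL/6J background. The study asked what the RNA-binding proteins Lin28a and Lin28b, known as blockers of let-7 microRNA maturation, do in lung branching and epithelial differentiation. Both genes had been deleted with a tamoxifen-inducible Cre recombinase driven from Nkx2-1, a transcription factor gene of the lung epithelium. The recombination removed exon 2 of each gene, which loxP sites flanked. There was 1 wild-type library (WT) and 2 double-knockout libraries (DKO 1 and DKO 2). The labels give neither age nor sex, nor whether the DKO libraries came from separate animals, so the spread between them may be partly technical. The values were RPKM of 16383 RefSeq transcripts, of which 11138 (68.0%) were listed at 0 in every library. The worth of 1 read, estimated from low values, put the depth at about 48700000 reads for WT, 30700000 for DKO 1 and 34200000 for DKO 2. A total of 2066 transcripts of 2058 genes had a mean of at least 1 RPKM and were tested. Coordinates are on GRCm38 (mm10).

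The first comparison asked whether the deleted genes were lower in the DKO libraries. Lin28b (NM_001031772, chromosome 10, 45376617 to 45486314) was present at a low level, with 0.449 RPKM in WT, 0.187 in DKO 1 and 0.590 in DKO 2. These values stand for about 118, 31 and 109 reads. The ratio of DKO 1 to WT was 0.417 (95% exact binomial interval 0.271 to 0.624), and that of DKO 2 to WT was 1.31 (1 to 1.72). These intervals cover counting error only. Lin28b was thus lower than WT in DKO 1 and not lower in the library labelled DKO 2, and over both libraries its log2 change was −0.08 (SE 0.32, limma adjusted p = 0.953 without a filter on low values). RPKM is summed over the whole transcript and over all cells of the lung, whereas the deletion takes out 1 exon in epithelial cells, so this level checks the labels only weakly. Lin28a was not analysed here. Nkx2-1, the gene that drives the recombinase, was listed at 0 in all 3 libraries, as were many genes of this table, and those zeros can be failed estimates.

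The second comparison asked which genes differed between the libraries labelled DKO and WT. Sftpc, which encodes surfactant protein C of distal lung epithelium and alveolar type 2 cells, fell the most (NM_011359, chromosome 14, 70520941 to 70524081). It had 369 RPKM in WT, 7.55 in DKO 1 and 0.0364 in DKO 2, or about 14243, 183 and 1 reads. WT was 48.9-fold above DKO 1 (95% exact Poisson interval 42.3 to 56.9), and the ratio of WT to DKO 2 was 10100 (1820 to 401000). On the log2(RPKM + 1) scale the change was −6.96 (SE 1.03, limma adjusted p = 0.0199). Cstdc5, a cystatin-domain gene of the stefin A cluster, rose (NM_001082546, chromosome 16, 36359382 to 36367570). It was listed at 0 in WT and had 23.4 RPKM in DKO 1 and 40.4 in DKO 2 (limma adjusted p = 0.0199). The size of its change on the log2 scale depends on the pseudocount and is not given.

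Sftpc and Cstdc5 were the 2 transcripts that passed limma with Benjamini-Hochberg adjustment, and 66 had an unadjusted p under 0.05, where chance gives about 103. The spread was estimated from the 2 DKO libraries alone, and the single WT library was assumed to vary like them. Both calls were lost without a filter on low values, with quantile normalization, with rescaling to TPM and with voom on approximate reads, that of Sftpc also with robust moderation and that of Cstdc5 with a pseudocount of 5. Over 13 alternatives the limma adjusted p ran from 1.07e-20 to 0.997 for Sftpc and from 1.3e-08 to 0.985 for Cstdc5. The stefin A cluster holds near-identical copies, so reads of Cstdc5 and its neighbour Cstdc4 are uncertain. Stfa1, of the same cluster, had 4.18 RPKM in WT and 7.64 in DKO 1 and was listed at 0 in DKO 2. The cluster as a whole was thus not silent in WT.

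By size alone, 97 transcripts differed from WT at least 2-fold in the same direction in both DKO libraries on the log2(RPKM + 1) scale, with the DKO libraries closer to each other than either was to WT. Of these, 66 were higher and 31 lower. With rescaling to TPM the split was 71 higher and 67 lower. Among the 12 genes furthest above WT, S100a8, a calcium-binding protein of neutrophils, had 3.04 RPKM in WT, 72.2 in DKO 1 and 108 in DKO 2 (log2 difference 4.46, SE 0.77, limma adjusted p = 0.0546). Camp, an antimicrobial peptide of neutrophil granules, was listed at 0 in WT, with 4.84 RPKM in DKO 1 and 9.32 in DKO 2. Wfdc17 stood at 4.33, 42.7 and 130.5 RPKM in the same order, and Cd52, a leukocyte surface protein, at 2.82, 39.1 and 27.1. Cstdc4 was listed at 0 in WT and had 8.37 and 12.9 RPKM in the DKO libraries. The metallothionein genes Mt2 (0.997, 20.3 and 69.5 RPKM) and Mt1 (28.9, 181 and 252 RPKM), whose products bind zinc and copper, were also among the 12. The others were Mxd4, Hsd3b6, Lgals7 and the Y-linked Eif2s3y. Other than Cstdc5, the limma adjusted p of these genes lay between 0.0546 and 0.517, so none of them passed.

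The 12 genes furthest below WT, other than Sftpc, had smaller differences, and none passed limma (adjusted p of 0.71 or above). Eno1b, a copy of the glycolytic enzyme gene Eno1, had 9.02 RPKM in WT, 0.925 in DKO 1 and 1.61 in DKO 2. Akr1c19 had 16.8, 4.93 and 2.66 RPKM, and Akr1c13, of the same aldo-keto reductase family, 4.83, 1 and 1.16. The kinase genes Mapk12 (4.63, 0.655 and 0 RPKM) and Map2k6 (2.34, 0.426 and 0.340 RPKM), which act in p38 signalling, were both in this group. Irx2, an Iroquois homeobox gene of lung epithelium, had 3.72, 1.07 and 0.297 RPKM. The remaining genes were Nudt10, Pjvk, Dynlt1f, Bcl2a1d and Ppp1r36. Eno1b, Dynlt1f, Bcl2a1d and the Akr1c genes have close paralogs, so their reads may be shared. In data simulated for this comparison on 2049 transcripts, 200 of them changed, 87.7 unchanged transcripts passed the 2-fold rule on average. A count close to the 97 seen here can thus arise without any change. In the same simulations limma recovered 31.6% of 4-fold, 92.5% of 16-fold and 99.4% of 64-fold changes. These rates depend on the 200 planted changes, which loosen the adjusted threshold. They do not carry over to these libraries, where S100a8 (log2 difference 4.46) and Mt2 (4.28) did not pass.

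**Figure D1:**
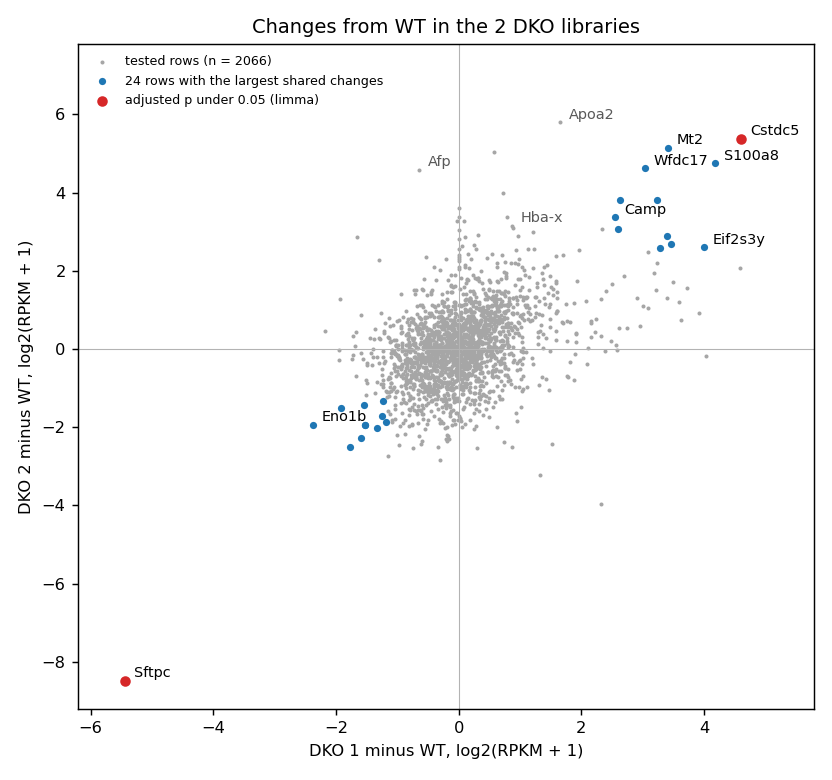
Difference from WT of each of the 2066 tested transcripts in DKO 1 (horizontal axis) and DKO 2 (vertical axis), both in log2(RPKM + 1). Red points passed limma (Sftpc at −5.44 and −8.48, and Cstdc5, which was listed at 0 in WT and whose place depends on the pseudocount), blue points are the rest of the 24 transcripts with the largest differences shared by both DKO libraries, and since both axes share the WT library, points lean to the diagonal even without any effect.

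The Y-linked genes differed in a way that bears on every comparison with WT. Ddx3y was listed at 0 in WT, with 5.49 RPKM in DKO 1 and 2.64 in DKO 2, and Eif2s3y was listed at 0 in WT, with 14.98 and 5.07 RPKM. Kdm5d (0, 1.03 and 0.219 RPKM) and Uty (0, 0.786 and 0.185 RPKM) followed the same order. Of the 2 Y-linked genes tested, 0 passed over all genes and 2 passed when adjusted over the list alone. By these genes the DKO libraries held male tissue, while WT had no Y-linked transcript above 0 among the 4, so sex was confounded with genotype in every comparison. All 4 were lower in DKO 2 than in DKO 1. No gene of the female-linked list was among these transcripts, so a library of both sexes could not be told apart from a male one.

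The third comparison concerned the epithelium, in which the genes were deleted. Apart from Sftpc, no tested epithelial marker passed limma, and few could be tested. Of the 30 genes fixed for the general epithelial list, 20 had a transcript here, and 10 of these were listed at 0 in every library. Of the 24 alveolar type 2 genes fixed, 5 were tested. Of the 4 tested genes of the general epithelial list, Epcam, an epithelial adhesion molecule, had 17.4 RPKM in WT, 6.75 in DKO 1 and 10.6 in DKO 2. Foxa1, a transcription factor of endoderm, had 2.64, 0.798 and 0.688 RPKM. Krt19, also in the list of mesothelial genes, lay above WT in both, with 3.08, 6.17 and 9.11 RPKM, and Krt18 on either side, with 12.2, 4.10 and 14.7 RPKM. Among 5 alveolar type 2 genes, Sftpc fell, while Ctsh (1.04, 2.39 and 2.92 RPKM) and S100g (0.214, 0.815 and 39.0 RPKM) did not pass. The list had a median log2 difference of −0.05 (camera adjusted p = 0.854), and 1 of its genes passed when adjusted over the list alone. The 3 tested alveolar type 1 genes, Igfbp2 (37.5, 81.5 and 79.8 RPKM), Akap5 (44.5, 56.1 and 90.8 RPKM) and Rtkn2 (1.44, 2.30 and 1.72 RPKM), were above WT in both libraries without passing.

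In the airway secretory list, 4 genes were tested and 0 passed. Sox2, a transcription factor of proximal airway epithelium, had 2.08 RPKM in WT, 0.996 in DKO 1 and 0.464 in DKO 2, and Aldh1a1 had 2.22, 1.38 and 0.590 RPKM. Among 3 basal cell genes, Krt17 was listed at 0 in WT, with 0.626 and 4.33 RPKM in the DKO libraries, and Snai2, which mesenchyme also expresses, had 21.9, 27.6 and 35.7 RPKM. The 2 tested neuroendocrine genes were Uchl1 (3.19, 2.81 and 0.357 RPKM) and Scg5 (2.53, 1.04 and 1 RPKM). No gene of these lists passed when adjusted over the list alone, and no ciliated cell gene reached the level for testing. Lists with fewer than 5 tested transcripts were given no test as a list. With no change at all, about 33% of transcripts would lie above a lone WT library in both DKO libraries, and as many below it.

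Genes of the distal epithelial tips, from which branching proceeds, had a median log2 difference of −0.62 over 9 transcripts and passed as a list (camera adjusted p = 0.0083, and adjusted p = 0.988 with an estimated correlation). With 1 residual degree of freedom, the estimated correlation gave all 28 lists the same adjusted p and could not tell them apart. The distal tip median was −0.22 in DKO 1 and −0.86 in DKO 2. Sftpc carried the call, since without it the adjusted p was 0.399, and the call was also lost without a filter on low values (0.558), with quantile normalization (0.0504), with TPM (0.107) and on ranks (0.0698). Of its members, 5 were below WT in both DKO libraries. Sox9, a transcription factor of the tips, had 3.84, 2.34 and 1.47 RPKM in WT, DKO 1 and DKO 2. Shh, the hedgehog ligand of lung epithelium, had 1.85, 1.46 and 0.0548 RPKM. Hmga2, a chromatin protein of fetal tissues, had 34.02, 18.2 and 20.8 RPKM. Only Sftpc passed as a single gene, over all genes and when adjusted over the list alone. Gata6 went the other way, with 4.19, 7.91 and 7.16 RPKM.

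The title of the study names signalling feedback loops, and 5 pathways were examined. In the FGF pathway, the ligand genes Fgf10 (1.71, 5.24 and 3.57 RPKM in WT, DKO 1 and DKO 2) and Fgf9 (1.10, 3.21 and 2.78 RPKM) were above WT in both DKO libraries. Fgf10 is also in the list of mesenchymal genes and Fgf9 in that of mesothelial genes. Spry1, a feedback inhibitor of FGF signalling, was below WT in both (2.52, 0.641 and 0.681 RPKM), whereas Spry2 was on either side (3.46, 5.11 and 1.46 RPKM). Fgf1 had 0.0158, 0.0917 and 3.34 RPKM. The list of 5 had a median log2 difference of 0.93, at percentile 98.42 of 10000 random lists of the same size and expression (camera adjusted p = 0.854), and 0 of its genes passed, whether over all genes or adjusted over the list alone.

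In the hedgehog list of 6 genes the median log2 difference was −0.08 (camera adjusted p = 0.945). Gas1, a hedgehog co-receptor gene, had 4.74, 10.96 and 8.58 RPKM, Foxf2 had 2.02, 3.07 and 4.88, and Gli3 had 3.01, 1.57 and 2.55. In the WNT list of 5 genes the median was 0.07 (camera adjusted p = 0.916). Sfrp2, a secreted WNT antagonist, had 8.68, 28.1 and 30.3 RPKM, Sfrp1 had 3.98, 4.29 and 5.11, Tcf7 had 2.15, 0.801 and 1.16, and Wnt4 had 1.55, 0.639 and 0.902. In the BMP and TGF-beta list of 13 genes the median was 0.03 (camera adjusted p = 0.854). Id3, a target of BMP signalling, had 35.0 RPKM in WT, 476 in DKO 1 and 105.5 in DKO 2, and Id1 had 40.6, 140.5 and 47.2. The ligand gene Tgfb3 had 0.497, 2.33 and 4.36 RPKM, and Bmp7 had 1.61, 0.542 and 1.01. In the Notch list of 5 genes the median was −0.01 (camera adjusted p = 0.914), with Dll3 at 0.0570, 1.97 and 1.35 RPKM and Notch2 at 1.04, 1.59 and 1.34. No gene of these 4 pathways passed limma, whether over all genes or adjusted over the list alone.

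**Figure D2:**
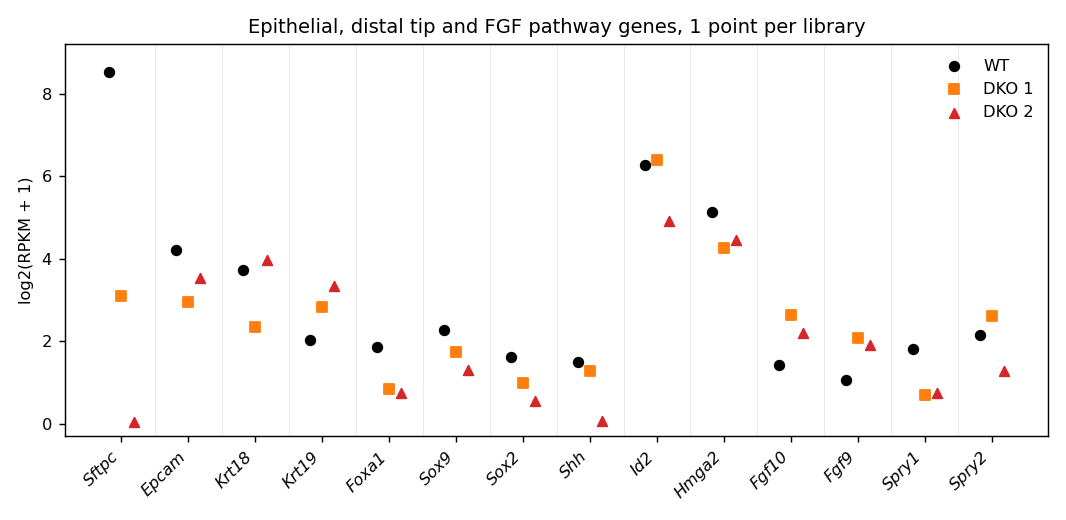
Level of 14 genes of the epithelium, the distal tips and the FGF pathway in each library, in log2(RPKM + 1) on the vertical axis, with 1 point per library and no error bars. Sftpc ran from 369 RPKM in WT to 7.55 in DKO 1 and 0.0364 in DKO 2, and it was the single gene among the 14 that passed limma.

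The question whether Lin28 acts through let-7 was addressed with 13 tested let-7 target genes. Their median log2 difference was 0.03, at percentile 49.34 of the random lists (camera adjusted p = 0.916), and 0 passed, whether over all genes or adjusted over the list alone. Hmga2, named above, was the target with the largest difference shared by both libraries (log2 difference −0.77, SE 0.74). Igf1r had 1.75, 1.37 and 0.498 RPKM in WT, DKO 1 and DKO 2, Ccnd1 had 14.1, 12.5 and 14.1, and Lrig2 had 0.448, 0.463 and 2.15. The 5 tested genes of fetal growth that often accompany Lin28 had a median of −0.08 (camera adjusted p = 0.916). At this number of libraries a change of a few-fold in single targets was often not detectable. RPKM was also summed over all cells of the lung, whereas the deletion was in epithelial cells. A median near that of random lists therefore does not answer the question for the epithelium.

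Among the lists of blood, immune cells and neighbouring organs, the immune, erythroid and liver lists passed camera at its preset correlation, each with a median above WT. None of these 3 passed with an estimated correlation (adjusted p = 0.988 for each) or with fry (adjusted p = 0.992 for each), and without a filter on low values the erythroid (0.064) and liver (0.264) calls were lost. The estimated correlation and fry rest on 1 residual degree of freedom. Each gave all 28 lists the same adjusted p, so neither could tell these lists from any other. The 11 immune genes had a median log2 difference of 1.18 (1.33 in DKO 1 and 1.02 in DKO 2, camera adjusted p = 7.17e-05, and adjusted p = 0.988 with an estimated correlation), and 8 were above WT in both. Besides S100a8 and Cd52 these included C1qb, a complement component made by macrophages (0.812, 19.4 and 4.90 RPKM), and the receptor adaptor Tyrobp (24.9, 219 and 52.3 RPKM). C1qc went apart, with 9.43, 25.1 and 0.111 RPKM. Over all genes 0 immune genes passed, and 3 did when adjusted over the list alone, namely S100a8, Cd52 and C1qb.

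The 9 erythroid genes had a median log2 difference of 1.39 (0.46 in DKO 1 and 2.20 in DKO 2, camera adjusted p = 7.17e-05, and adjusted p = 0.988 with an estimated correlation). The embryonic globin genes Hba-x (679.5, 1240 and 6023 RPKM in WT, DKO 1 and DKO 2) and Hbb-bh1 (1158, 2195 and 5338 RPKM) were among them, as was the erythroid regulator Klf1 (0.0803, 0.340 and 7.18 RPKM). The 5 liver genes had a median of 1.97 (0.32 in DKO 1 and 3.98 in DKO 2, camera adjusted p = 0.000501, and adjusted p = 0.988 with an estimated correlation). Apoa2 had 0.236, 2.88 and 67.7 RPKM, Apoa1 had 5.34, 6.93 and 21.3, and albumin (Alb) was listed at 0 in WT, with 0.654 and 14.8. Without albumin the liver medians were 0.15 in DKO 1 and 3.93 in DKO 2. Over all genes 0 of either list passed, and when adjusted over the list alone 1 liver gene (Apoa2) and 0 erythroid genes did. The 5 heart muscle genes had a median of −0.37 in DKO 1 and 2.56 in DKO 2 and did not pass as a list (camera adjusted p = 0.286), with Actc1 at 2.01, 2.23 and 20.8 RPKM. Without Myl2, which was listed at 0 in WT, the heart medians were −0.53 and 2.31.

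**Figure D3:**
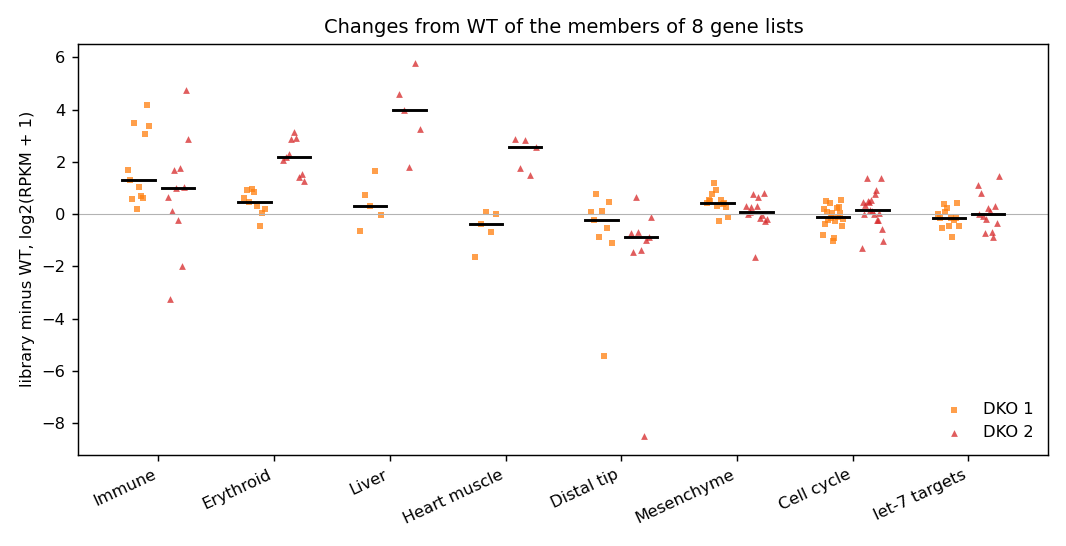
Difference from WT, in log2(RPKM + 1) on the vertical axis, of the tested members of 8 gene lists in DKO 1 (squares) and DKO 2 (triangles), with a bar at each median. The liver medians were 0.32 in DKO 1 and 3.98 in DKO 2, the heart muscle medians −0.37 and 2.56, and the immune medians 1.33 and 1.02.

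The stromal and vascular lists did not pass. The median log2 difference was 0.27 for 13 mesenchymal genes, −0.01 for 10 genes of the fibrillar matrix, −0.05 for 5 smooth muscle genes and 0.22 for 6 endothelial genes (camera adjusted p of 0.854, 0.916, 0.945 and 0.854). The 28 lists with at least 5 tested transcripts thus held 4 that passed at the preset correlation, and the smallest adjusted p among the others was 0.286.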

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

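The tests on genes with 1 RefSeq transcript, on GC content, with voom and on lists without Sftpc or without transcripts at 0 in WT were chosen after seeing the data. The number of genes passing limma was 2 and became 13 with a pseudocount of 0.1, 1 with a pseudocount of 5, 10 with a filter at 5 RPKM, 9 with median scaling, 14 without haemoglobin, mitochondrial and sex-linked genes, and 7 after removing the GC trend. It was 0 without a filter (260 at an unadjusted p under 0.05), 0 with quantile normalization (45), 0 with TPM (38) and 0 with voom (34). It was 3 without a variance trend and 2 with robust moderation, where S100a8 took the place of Sftpc (adjusted p = 0.232). The 2-fold rule gave 97 transcripts, and 166 with a pseudocount of 0.1, 34 with a pseudocount of 5, 50 with a filter at 5 RPKM and 275 at 1.5-fold; leaving out 1 DKO library gave 280 to 555, since 1 library then had to pass. The number of lists passing was 4, and 2 without a filter (immune and mesothelium, with erythroid, liver and distal tip lost). It was 0 with an estimated correlation and 0 with fry. With a filter at 5 RPKM, 9 lists could be tested and 2 passed (immune and erythroid), while liver and distal tip were untested. The remaining settings gave 3 or 4. Distal tip was lost under quantile normalization, TPM, ranks and without Sftpc. Liver was untested among genes with 1 RefSeq transcript and without transcripts at 0 in WT. The log2 change of Lin28b was −0.08, ran from −0.30 to −0.02 over pseudocounts and scalings, and from −0.287 to 0.134 when 1 DKO library was left out, with the sign reversed without DKO 1. Ccnd1 reversed from −0.09 to 0.05 without haemoglobin, mitochondrial and sex-linked genes, because that setting rescales the remaining transcripts to each library's former total. Of the other values of single genes under settings with a test, 817 kept direction and side of the threshold, 41 came to pass and 10, all of Sftpc or Cstdc5, ceased to. Without 1 DKO library, which leaves no test, 172 values of single genes kept their direction, as their choice from genes on the same side of WT in both libraries requires, and 8 medians of the passing lists kept theirs. The cause of the other shifts was not tested. TPM moved the median change of all tested transcripts from −0.01 to −0.22, so changes under TPM stand relative to that shift. Without 1 DKO library no residual degrees of freedom remain, so gene calls and list tests have no value there. With all libraries 1 remains, and the estimated correlation and fry each gave every list the same adjusted p, so they could not tell lists apart. No paired analysis was possible because there is 1 WT library and the groups share fewer than 2 replicate numbers. Depth limits low genes most, as with the 31 reads of Lin28b in DKO 1.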

Other observations

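Beyond the lists described above, cell cycle genes did not pass as a list. Their median log2 difference was 0.04 over 19 transcripts (camera adjusted p = 0.984), with Mki67, a marker of cycling cells, at 14.3, 7.87 and 5.33 RPKM in WT, DKO 1 and DKO 2, Top2a at 25.5, 22.3 and 12.1, and Plk1 at 1.08, 2.06 and 4.37. The 9 Hox genes, which mark position along the body axis, had a median of 0.25 (adjusted p = 0.914), with Hoxa5, a lung mesenchyme gene, at 48.4, 29.5 and 28.1 RPKM. The 6 imprinted genes had a median of 0.02 (adjusted p = 0.854), with Phlda2 listed at 0 in WT and at 4.64 and 2.14 RPKM in the DKO libraries. In the list of 3 mesothelial genes, Aldh1a2, which makes retinoic acid, had 3.75, 11.4 and 13.8 RPKM. The others were Krt19 and Fgf9, described above under epithelium and the FGF pathway, and all 3 were above WT in both DKO libraries. Whole-lung values cannot assign Krt19 or Fgf9 to 1 of these lists. Among 17 genes of oxidative phosphorylation (median −0.10, adjusted p = 0.854), Cox6a1 had 851, 7938 and 2411 RPKM and Cox8a 503, 5302 and 1241. The median was −0.09 for 36 ribosomal protein genes, −0.06 for 6 glycolytic genes, 0.10 for 5 p53 targets, −0.44 for 6 hypoxia genes, −0.11 for 8 immediate early genes, −0.44 for 6 heat shock genes and 0.29 for 5 histone genes (camera adjusted p between 0.854 and 0.945). No gene named in this paragraph passed limma.

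The tests of fewer epithelial cells, of fewer distal tip cells, of developmental stage, of the share of organ transcripts and of the count by the 2-fold rule in other groupings were chosen after the result was seen. The 3 libraries can be set 1 against 2 in 3 ways, too few for a share under 0.05. The genotype grouping gave 97 transcripts by the 2-fold rule, and the highest of the others 282, so that all 3 groupings gave as many. It gave 2 limma calls against 0 in the others (1 of 3 groupings as high), and 4 lists against at most 5 (3 of 3). The same lists passed in groupings that set genotype aside, erythroid (camera adjusted p = 3.52e-06), liver (4.37e-06) and distal tip (0.0491) with DKO 2 as the lone library and immune (2.12e-05) with DKO 1 as the lone library. With DKO 2 set apart, the counts by the 2-fold rule and of lists were the highest of the 3 groupings, as was the number at an unadjusted p under 0.05 (284, against 66 in each other grouping), while limma called 0 there. Lists that did not pass by genotype passed in these groupings as well. These were heart muscle and histone genes with either DKO library as the lone one, and ribosomal protein genes with DKO 1. The larger counts by size point to a structure in which DKO 2 stands further from the other libraries.

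The fall of Sftpc in both DKO libraries, to 7.55 RPKM in DKO 1 and to near absence in DKO 2, is the largest difference among the tested transcripts. Fewer epithelial cells, or fewer distal tip cells, would lower their other genes as well. The median log2 difference was −0.76 for the 4 other tested epithelial genes and −0.61 for the 8 other distal tip genes (from −0.82 to 0.72), against −6.96 for Sftpc. Most of these genes had only a few RPKM in WT. With a pseudocount of 1 none could fall as far as Sftpc, so these medians cannot decide. In RPKM, Epcam (17.4, 6.75 and 10.6 in WT, DKO 1 and DKO 2) and Krt18 (12.2, 4.10 and 14.7) were not lost as Sftpc was. In DKO 2, Foxa1 (0.688 RPKM against 2.64 in WT) and Shh (0.0548 against 1.85) fell further. A GC trend was present in DKO 2, yet after its removal the change of Sftpc was −7.13. Random loss of abundant transcripts was not seen, since of 286 other transcripts with at least 5000 approximate reads in WT, 0 were 16-fold lower in either DKO library, for 0 expected in both by independent losses. What stays open is a lower level of Sftpc itself after deletion of Lin28a and Lin28b, which was not tested. A partial loss of all epithelial cells alike would lower Epcam and Krt18 as far as Sftpc in RPKM. The values of these 2 genes argue against it as the whole account of the fall, though not as a part of it. A loss of distal tip cells and the difference in sex stay open too. So does a difference in developmental stage, which the labels do not give and which cannot be told apart here. Hmga2 differed by −0.77 without passing. As it is also in the let-7 target list, its level could not separate stage from the deletion in any case.

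DKO 2 held liver, heart and erythroid transcripts together, and 83.3% of the transcripts of these lists seen in any library (25 of 30) were highest in it, against 30.5% of all 5245 transcripts seen. The lists were singled out because DKO 2 was high in them, so this share cannot tell whether cells of neighbouring organs or blood were in that library, and of the immune transcripts 13 of 19 were highest in DKO 1 and 5 in DKO 2. The most abundant tested gene of each list in DKO 2 was Hbb-y for erythroid (91331 RPKM), Afp for liver (70.0) and Myl4 for heart (56.1), while in WT 2 of 5 liver, 4 of 5 heart and 7 of 9 erythroid genes reached 1 RPKM, and 1 (Afp) is in another list. GC content does not account for it, because the median change in DKO 2 was 2.56 before and 2.35 after removal of the trend over 19 transcripts. Cells of other organs or blood remain open, and a change in blood content from the deletion remains open for the erythroid transcripts alone. A difference in developmental stage, which the labels do not give, was not tested for these transcripts. It remains open too, as the erythroid list holds embryonic globin genes.

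In WT, 11 transcripts were listed at 0 while both DKO libraries had at least 50 approximate reads, among them Cstdc5, Cstdc4, Camp and Phlda2. Random loss of transcripts in single libraries may account for some of them, as the same count was 11 in WT, 3 in DKO 1 and 45 in DKO 2. The count takes no account of level. Cstdc5 had 23.4 RPKM in DKO 1 and 40.4 in DKO 2. The highest of the 45 transcripts at 0 in DKO 2 was Stfa1, with 7.64 RPKM in DKO 1. Loss of a transcript as high as Cstdc5 was thus not seen there. A difference in sex covers 27.3% of the 11 transcripts in WT, the 3 on the Y chromosome (Ddx3y, Eif2s3y and Kdm5d). The others are not on the Y chromosome, and an effect of sex on them was not tested. For the neutrophil genes S100a8 and Camp, a higher content of immune cells in the DKO libraries also remains open.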
